A study of Caenorhabditis elegans with 2 samples.

How the data were processed

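The samples were 2 biological replicates of whole C. elegans young adults (64 hours) of a strain with a fosmid transgene for NHR-120 fused to GFP, sonicated and precipitated with an antibody against GFP, per the labels' descriptions. The labels name a possible control experiment, which was not analysed here. The assembly is ce11, per the labels and the deposited file descriptions. Aligner, peak caller, their versions and the use of a control are not given in the sources used here. The series' files comprise 8 peak lists, 4 thresholded and 4 ranked: for both replicates together a main thresholded list, a conservative thresholded list and 2 ranked lists, and for each replicate a thresholded and a ranked list. Per the deposited file descriptions, the joint lists derive from both replicates' alignments and the others from 1 alignment each, and every list has 1 further input whose role is not stated. The thresholded lists have 1 more input, which the ranked lists lack and whose role is not stated either, per the deposited file descriptions. Signal tracks were not analysed here.

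The deposited lists hold, for each peak, a score scaled by the authors to at most 1000, a signal value whose scale is not stated, a −log10 q value and a summit position. The deposited ranked lists also hold the −log10 of the global irreproducible discovery rate (IDR), a measure of how reproducible a peak's rank is between the lists compared. In one deposited ranked list, 2 further columns hold the paired signal values of the lists the authors compared, and no replicate was assigned to either, since the columns carry no sample names. In the other ranked list, 2 such signal columns were not used. Tested on the lists, all 610 main peaks had a global IDR of at most 0.01 in this other ranked list. All 555 conservative peaks had one in the ranked list whose paired signals were used. A limit of 0.01 is therefore the threshold the lists show. The IDR of the main list comes from a different comparison, which was not shown to be between the replicates. The lists give no read counts, so depth per sample is unknown, and intervals cover only the counting error of peaks or genes. Scores were used only to describe the lists, and q values only to break ties in rank and to describe named peaks. Signal values served to rank and describe peaks, to compare the paired columns of 1 ranked list across peaks, and to compare regions and unlisted peaks with the other peaks of the same ranked list.

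The main list was the larger thresholded list. The background for tests of location was the ranked list of 115573 peaks without those that overlap the main list. Gene models came from Ensembl release 115 (WBcel235, the assembly named ce11 by the authors, with the same chromosome names apart from a prefix and all peaks within the chromosome lengths), and symbols missing there came from RefSeq by WormBase identifier. Peaks were placed by their summit in 5 classes: within 1 kb of a protein-coding TSS, within 1 kb of the TSS of a non-coding RNA gene only, exon, intron, or intergenic. Of 46890 annotated genes, 34887 had a ranked summit within 1 kb of a TSS and served as background for the RNA-gene lists, and 17792 of 19973 protein-coding genes served for the other lists. Genes with a main-list summit within 1 kb of a TSS numbered 871, of which 343 are protein-coding and 69 are piRNA genes, so neighbouring genes often share a peak. Gene lists (35: 30 of protein-coding genes and 5 of RNA genes), words, named-gene rule, tests and most alternative settings were set before the data were examined. The named peaks are the 25 with the highest signal, each named by the nearest TSS, with a second gene where a start lies within 1 kb on the other side of the summit, plus up to 4 members of each list with the strongest peak, nhr-120 and unc-119.

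Shares were compared with two-sided Fisher's exact tests, 95% intervals of odds ratios by the Woolf method, 95% Wilson intervals of shares, and Benjamini-Hochberg adjustment within each family (5 classes, 6 chromosomes, 35 lists, 12 words, 2080 words of 6 bases), with a threshold of 0.05 on the adjusted p. A count of 0 had 0.5 added to each cell for the odds ratio. Words on either strand were counted within 100 bp of the summit and compared with 10 ranked peaks per peak from the same class and GC decile (seed 1). Replicate overlap was tested with 100000 random draws, and the interval of the Spearman correlation came from 1000 bootstrap draws of peaks. Repeated sequence was measured as the share of a peak's 30-base words found more than once in the genome on either strand. Peaks near short RNA genes are those with a tRNA, snoRNA, snRNA, rRNA or microRNA start within 1 kb.

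The tests were tested on simulated data. In lists drawn at random from the 115573 ranked peaks, at least 1 call was made in 2 of 40 lists for location, 0 of 40 for chromosomes, 2 of 40 for gene lists and 2 of 40 for words. With 200 peaks at tRNA or snoRNA genes, 200 on chromosome X and AGGTCA written into 200 peaks, each was recovered in 10 of 10 lists. AGGTCA written into 40 peaks was recovered in 10 of 10 lists and into 20 peaks in 5 of 10. Fewer than 200 added peaks were not tried for chromosomes or gene lists. How well those tests find smaller effects is therefore unknown. Alternatives tried were the conservative list, the upper 50% of the list by signal, each replicate's own list, TSS windows of 500 bp and 2 kb, nearest-TSS assignment, other backgrounds, word windows of 50 and 200 bp, other overlap rules, and settings added later that leave out peaks near tRNA or short RNA genes or piRNA genes. An expectation written for GC content as the source of an AGGTCA enrichment was not pursued, since no enrichment was called. The tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.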

Results

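Chromatin immunoprecipitation with sequencing was used to map where NHR-120, a nuclear hormone receptor of Caenorhabditis elegans, was found on the genome of whole young adult worms. The worms carried an integrated fosmid transgene that makes NHR-120 fused to green fluorescent protein (GFP), together with a copy of unc-119 that rescues an unc-119 mutation, and the fusion protein was precipitated with an antibody against GFP. Nuclear hormone receptors are transcription factors with a zinc-finger DNA-binding domain, a family that is greatly expanded in nematodes. The series has 1 group with 2 biological replicates, each taken at 64 hours from synchronised cultures, so the design implies no contrast between conditions. The questions it allows are where the peaks lie, which genes they mark, and whether the replicates give the same sites. Control immunoprecipitations were not analysed here, and read depth is unknown because the lists give no counts. Signal values of peaks are the authors' own.

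NHR-120::GFP peaks were few at the authors' threshold, and the strongest of them were found in both replicates. The thresholded list built from both replicates held 610 peaks with a median width of 264 bp, which together covered 0.159% of the genome. Of these, 18 overlapped the next peak along the chromosome, and the counts and tests by peak took each as a separate peak. The authors' conservative list held 555 peaks, and 439 of these had the same interval in the longer list. The IDR values behind these lists came from different ranked lists. Not all of the 610 peaks were therefore shown to pass a threshold between replicates. Thresholded on its own, replicate 1 gave 89 peaks and replicate 2 gave 96. Of the 89 peaks of replicate 1, 48 (53.9%, 95% Wilson interval 43.6 to 63.9%) overlapped a peak of replicate 2 by at least 1 bp. Lists of the same lengths drawn from each replicate's own ranked peaks shared 0.0778 peaks on average and at most 3 (one-sided permutation test with 100000 draws, p = 1.0e-05, the smallest the draws can give). The draws took no account of signal, so this p does not separate binding from any other strong feature shared by the replicates. Of the 610 peaks, 47 overlapped both replicates' own lists, 37 overlapped that of replicate 1 only, 42 overlapped that of replicate 2 only, and 484 overlapped neither. Across the 608 peaks with paired signal values, the signals of the paired lists had a Spearman correlation of 0.135 (95% bootstrap interval 0.0495 to 0.221) and a Pearson correlation of log2 values of 0.31. These correlations are across peaks, which are not independent replicates. The 608 peaks had also passed a threshold, and such a selection can lower a correlation. Over all 114571 ranked peaks with paired signals the Spearman correlation was 0.255.

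Genes for transfer RNAs had the largest odds ratio of the gene lists in the joint list. Of 590 tRNA genes that had any ranked peak within 1 kb of their start, 138 (23.4%, 95% Wilson interval 20.2 to 27%) had a summit of the thresholded list there, against 2.14% of all other genes. The odds ratio was 14 (95% interval 11.4 to 17.1, two-sided Fisher's exact test with Benjamini-Hochberg adjustment over 35 gene lists, adjusted exact p = 1.99e-91). Many tRNA genes lie in groups that share a peak, and the strongest peaks of the 138 genes were 97 different peaks. Counted by peak, 100 of the 610 peaks had a tRNA gene start within 1 kb, against 1.08% of the 114942 other ranked peaks. The summits sat on the genes themselves: the median summit lay 32.5 bp into the tRNA gene, 67 of the 100 summits were inside the annotated gene, and 96 were within 250 bp of its start. Among other ranked peaks within 1 kb of a tRNA gene, 35.0% were within 250 bp. The tRNA genes with the strongest nearby peaks were ZK994.t2, whose peak lies at -914 bp from its start beside a snoRNA gene, then the neighbours F15G9.t1 and F15G9.t2, and C04A11.t1. The peak at F15G9.t1 and F15G9.t2 (X, 9743526 to 9743789, ce11, over the exon of F15G9.t1) had a signal of 166. The peak at C04A11.t1 (X, 13665482 to 13665745, in the intron of that gene) had a signal of 137, and both of these peaks were in both replicates' own lists. Sequence is shared between copies of tRNA genes: a median of 23.6% of the 30-base words in the tRNA peaks occur more than once in the genome.

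Small nucleolar RNA genes, whose products guide modification of ribosomal RNA, were also enriched. In the list of replicate 2 alone their odds ratio was 17.7 against 10 for tRNA genes, and in that of replicate 1 alone 14.7 against 15.7, and the difference between the classes was not tested. Of 328 snoRNA genes, 52 (15.9%, 95% Wilson interval 12.3 to 20.2%) had a summit within 1 kb, against 2.37% of other genes (odds ratio 7.76, 95% interval 5.73 to 10.5, adjusted exact p = 3.21e-25 by Fisher's exact test). Here the summits lay just before the gene. The median distance of summit minus start was -26 bp, and 27 of 51 summits fell in the 100 bp upstream, against 7.11% for other ranked peaks near snoRNA genes. The strongest peak of the whole list (V, 8500476 to 8500606, signal 284) was at -29 bp from the start of the snoRNA gene ZK994.7, in an intron of pxn-1. The neighbouring snoRNA genes C51F7.4 and C51F7.3 shared the third strongest peak (V, 12303491 to 12303754, signal 253), and T03F7.8 had the sixth (V, 11314100 to 11314363, signal 204). These 3 peaks were in both replicates' own lists.

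Small nuclear RNA genes showed a weaker excess, with 9 of 116 marked (7.76%, odds ratio 3.31, 95% interval 1.67 to 6.55, adjusted exact p = 0.0224). They included sls-2.4 (I, 4172187 to 4172450, signal 122) and sls-2.1 (II, 5844708 to 5844971, signal 122), which encode spliced leader RNAs that are trans-spliced onto messenger RNAs, R07E5.16 (III, 10989567 to 10989830, signal 117, a symbol that the annotation also gives to a gene on IV), and M163.13 (X, 14476726 to 14476989, signal 88.1). The call was lost with a TSS window of 2 kb (odds ratio 2.07, adjusted exact p = 0.21), in the upper 50% of peaks by signal (3.2, adjusted exact p = 0.166), in the list of replicate 2 alone (7.07, adjusted exact p = 0.0889), and when piRNA genes were left out of the background, a setting chosen after seeing the data (odds ratio 2.89, adjusted exact p = 0.0529). MicroRNA genes did not stand out (5 of 234, odds ratio 0.852, 95% interval 0.350 to 2.07). Those with the strongest peaks were cel-mir-80 (signal 102), cel-mir-4936 (signal 84.2), cel-mir-52 (signal 83.9) and mir-2214 (signal 77.3). None of 10 ribosomal RNA genes had a summit of the thresholded list. Past the IDR threshold but outside that list, 3 peaks on V had a ribosomal RNA gene as the nearest start. These are 3 different genes that share the symbol rrn-4.2. Each summit was measured from its own gene, at -238, 230 and 140 bp. Their signals were 99.6, 95.9 and 76.4, with 65.5%, 74.5% and 88.9% repeated words. The peaks at 230 and 140 bp also had the start of an snRNA gene named sls-1.10 within 1 kb, at 573 and 663 bp.

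**Figure D1:**
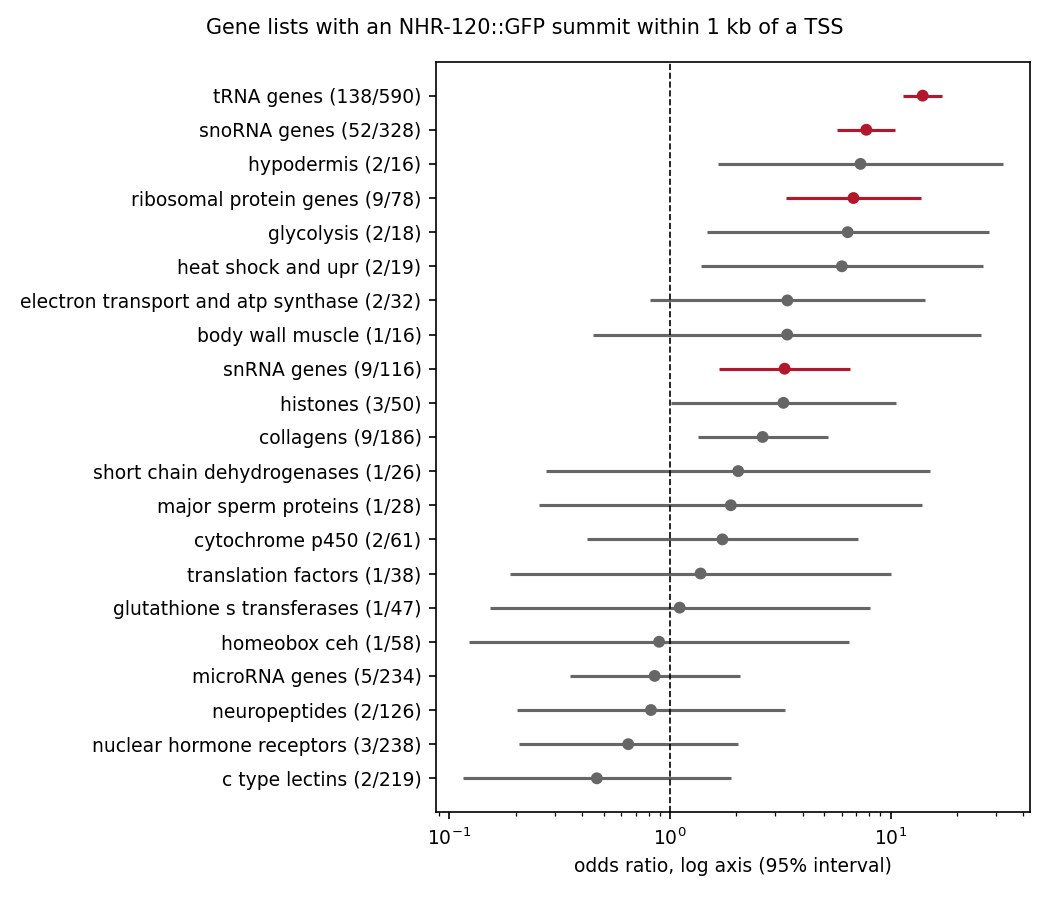
Odds ratio (log axis) with 95% interval for each gene list that had at least 1 gene with a summit within 1 kb of a TSS; marked and tested genes are in parentheses, and red marks an adjusted p under 0.05. tRNA genes (138 of 590) and snoRNA genes (52 of 328) lie furthest from the dashed line at an odds ratio of 1.

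**Figure D2:**
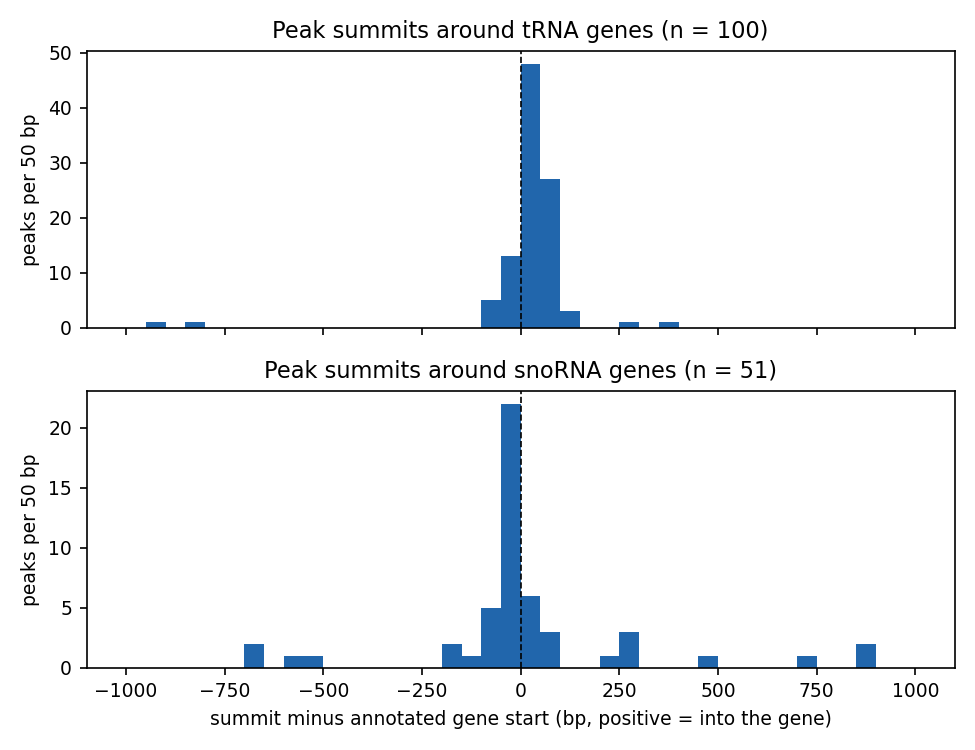
Number of thresholded peaks per 50 bp by distance (bp) from the summit to the start of the nearest tRNA gene (100 peaks, upper) or snoRNA gene (51 peaks, lower), with positive values inside or beyond the start in the direction of the gene. The tRNA summits centre 32.5 bp into the gene, and those at snoRNA genes lie mostly in the 100 bp upstream.

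Ribosomal protein genes were the protein-coding list with an excess of peaks. A summit was found at 9 of 78 (11.5%), against 1.89% of other protein-coding genes (odds ratio 6.79, 95% interval 3.36 to 13.7, adjusted exact p = 0.000219 by Fisher's exact test). The strongest were rpl-3 (III, 3867445 to 3867708, summit minus TSS -277 bp, signal 191), rpl-35 (III, 7854585 to 7854848, -417 bp, signal 149), rpl-20 (IV, 4749960 to 4750223, -314 bp, signal 138) and rpl-15 (IV, 654801 to 655064, -357 bp, signal 108), all with the summit between genes. The peaks of rpl-3, rpl-35 and rpl-20 were in both replicates' own lists. The other members are named after their values were seen. Summits lay upstream of rps-19 (-307 bp) and rps-23 (-281 bp). They lay past the start at rpl-43 (572 bp, in an exon of xrn-2), rps-25 (732 bp, between genes) and rps-13 (720 bp, in its exon). Of the 9 genes, 3 shared their peak with a short RNA gene start, namely rpl-15, rps-23 and rps-13. The summit at rpl-15 lay at -572 bp from the start of the snoRNA gene K11H12.13. Without such peaks 6 of 78 remained (odds ratio 5.49, adjusted exact p = 0.0364, a setting chosen after seeing the data). The odds ratio was 13.4 in the list of replicate 2 alone, 14.3 in that of replicate 1 alone and 14 in the upper 50% of peaks by signal. When each peak was given only to its nearest TSS the call was lost (odds ratio 3.52, adjusted exact p = 0.345). Without a second group, occupancy that does not need NHR-120 cannot be told apart from binding at these genes either.

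The list of genes named col, dpy, sqt, rol and bli, most of which encode cuticle collagens of the worm's exoskeleton, had 9 of 186 genes with a summit (4.84%, odds ratio 2.63, 95% interval 1.33 to 5.18, adjusted exact p = 0.0714), which missed the threshold. Examples were col-39 (signal 87.3, 481 bp into the gene), col-122 (signal 86.9, 316 bp into the gene) and col-103 (signal 84.6, 965 bp into the gene), each with the summit in an exon, and col-185 (signal 85.5), whose peak lies at a tRNA gene. Of the 9, dpy-11 encodes a thioredoxin-related protein and not a collagen, its peak lies in an exon of mdh-1, and it is named after its values were seen. The list passed the threshold when each peak went to its nearest TSS only (odds ratio 4.03, adjusted exact p = 0.0153), with a TSS window of 2 kb (odds ratio 3.05, adjusted exact p = 0.00147) and with all annotated genes as background (odds ratio 2.83, adjusted exact p = 0.0456), and its odds ratio was 0.869 in the list of replicate 2 alone.

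Other lists had 1 to 3 members with a summit, and no adjusted p under 0.05. The heat shock and unfolded protein list had hsp-90, a cytosolic chaperone (signal 94.8), and hsp-60, a mitochondrial chaperonin (signal 87.3), as 2 of 19 genes (adjusted exact p = 0.223). The glycolysis list had gpd-3 (signal 84.4) and gpd-1 (signal 71.8), which encode glyceraldehyde-3-phosphate dehydrogenase, as 2 of 18 genes (adjusted exact p = 0.223). Both gpd peaks hold repeated sequence, with 45.1% and 46.0% of 30-base words found more than once, so the copy that the reads came from is uncertain. Among histone genes, his-37 (signal 81.1) and the neighbours his-1 and his-2, which share a peak (signal 78.6, 33.6% repeated words), were marked, 3 of 50 genes (odds ratio 3.27, adjusted exact p = 0.279), and this list passed the threshold in the conservative list (odds ratio 6.06, adjusted exact p = 0.0147). Electron transport and ATP synthase genes had cox-5A (signal 82.7) and nuo-5 (signal 74.7) of 32, and translation factors had iff-2 (signal 96.1) of 38. The peak of iff-2 also lies within 1 kb of the snoRNA gene F54C9.12 and of F54C9.14. Nuclear hormone receptor genes had 3 of 238, namely nhr-255, nhr-241 and nhr-239, with an odds ratio of 0.646 (95% interval 0.206 to 2.03), and the peak at nhr-255 lies at a tRNA gene. Cytochrome P450 genes had 2 of 61 (cyp-14A4 and cyp-33C5), C-type lectins 2 of 219 (clec-145 and clec-83), neuropeptides 2 of 126 (ins-39 and nlp-4), glutathione S-transferases 1 of 47 (gst-27), short-chain dehydrogenases 1 of 26 (dhs-8), ceh homeobox genes 1 of 58 (ceh-2) and major sperm proteins 1 of 28 (msp-33). The peaks of cyp-14A4 and ceh-2 lie at the tRNA genes R04D3.t4 and C27A12.t1, and those of gst-27 and nlp-4 at the snoRNA genes Y53F4B.48 and F59C6.15. The peak of msp-33 has 77.9% repeated words, so its assignment among the near-identical msp genes is uncertain.

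Lists of known genes of single tissues had from 0 to 2 members with a summit, and no adjusted p under 0.05. Among protein-coding genes outside the intestine list, for comparison, 1.93% had one. The hypodermis list had ajm-1 (signal 95.9, at a tRNA gene cluster) and col-19 (signal 67.9, in its exon) of 16 genes (odds ratio 7.30, adjusted exact p = 0.217), and body wall muscle had unc-89 of 16 (signal 78.3, in an intron, adjusted exact p = 0.852). None of the tested genes had a summit in the lists for intestine (0 of 19), pharynx (0 of 12), neurons (0 of 19) or germline (0 of 23). None was found either for fat and peroxisome metabolism (0 of 40), the propionate shunt and vitamin B12 response (0 of 15), oxidative and insulin stress (0 of 20), glucuronosyltransferases (0 of 53), vitellogenins (0 of 6), the proteasome (0 of 32), the vacuolar ATPase (0 of 20), acyl-CoA synthetases (0 of 23) or lipases (0 of 8). The upper 95% Wilson bound is 6.76% with 0 of 53 genes, 8.76% with 0 of 40, 16.8% with 0 of 19 and 39% with 0 of 6. These lists are therefore too short to exclude a moderate excess, and the shorter ones a large excess. The tissue is the whole worm, so the lists describe which known genes carried peaks and not cell types.

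Peaks lay near gene starts more often than the ranked peaks that did not overlap the list. Of 610 summits, 298 (48.9%, 95% Wilson interval 44.9 to 52.8%) were within 1 kb of the start of a protein-coding gene, against 42.3% of the background (odds ratio 1.30, 95% interval 1.11 to 1.52, adjusted exact p = 0.00167 over 5 classes). A further 120 (19.7%) were within 1 kb of the start of a non-coding RNA gene only, against 9.81% (odds ratio 2.25, adjusted exact p = 1.65e-12). The odds ratio of this class was 3.15 in the list of replicate 2 alone, 3.66 in that of replicate 1 alone and 4.17 with a TSS window of 500 bp. Summits in exons away from gene starts made up 10% against 18.8% (odds ratio 0.481, adjusted exact p = 5.51e-09), and those in introns 7.21% against 15.4% (odds ratio 0.426, adjusted exact p = 3.22e-09). Intergenic summits did not differ detectably (14.3% against 13.6%, odds ratio 1.06, 95% interval 0.840 to 1.32). The call at protein-coding starts was lost in the upper 50% of peaks by signal (odds ratio 1.15, adjusted exact p = 0.279) and with a TSS window of 2 kb (1.13, adjusted exact p = 0.21), and no excess was found in the lists of the single replicates (0.961 and 0.998). Without peaks near short RNA genes, the class of non-coding RNA starts was depleted (odds ratio 0.663, adjusted exact p = 0.0411), a setting chosen after seeing the data.

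By chromosome, X held 135 peaks (22.1% against 17.6% of the background, odds ratio 1.33, 95% interval 1.1 to 1.61, adjusted exact p = 0.0120 over 6 chromosomes), and chromosome II held fewer than its share (70 peaks, 11.5% against 16.3%, odds ratio 0.667, 95% interval 0.520 to 0.856, adjusted exact p = 0.00569). Chromosomes I, III, IV and V did not pass the threshold. Of the tested tRNA genes, 46.1% lie on X. Without the peaks within 1 kb of a tRNA gene, X held 82 of 510 peaks, against 17.3% of the background (odds ratio 0.915, 95% interval 0.722 to 1.16, adjusted exact p = 0.622), and the odds ratio of chromosome II was 0.721 (adjusted exact p = 0.0825), in a comparison chosen after seeing the data. Neither chromosome passed in the lists of replicate 2 and replicate 1 alone, where X had odds ratios of 1.3 and 1.78, and chromosome II of 0.933 and 1.06.

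Of the 25 peaks with the highest signal, 24 overlapped a peak in both replicates' own lists, the exception being the peak in an intron of mdt-26, a Mediator subunit (II, 5661669 to 5661932, signal 176). The nearest gene start was that of a snoRNA for 7 of the 25, of a protein-coding gene for 11, of a non-coding RNA for 3, of a long intergenic non-coding RNA for 1, of a pseudogene for 2 and of a tRNA for 1. The second strongest peak (I, 4769571 to 4769692, signal 254) lay between the long non-coding RNA gene M04F3.7 and rpa-2, and 83.9% of its 30-base words are repeated in the genome. The fourth (IV, 4725563 to 4725674, signal 232), nearest to the non-coding gene K08F11.7, consists wholly of repeated words (100%). The fifth (I, 10462616 to 10462879, signal 213) is intergenic, with the pseudogene Y106G6H.10 as its nearest start at 4920 bp. The remaining snoRNA genes among the 25 were W03C9.9 (II, 11960820 to 11960894, signal 194), Y23H5B.10 (I, 2514232 to 2514495, signal 169), ZK265.10 (I, 8259436 to 8259699, signal 150.2) and B0334.12 (II, 11484642 to 11484905, signal 143, in an intron of twk-5). The RNA component of ribonuclease P, rpr-1, also had a peak on its exon (I, 13463829 to 13464092, summit 6 bp into the gene, signal 147).

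Protein-coding genes among the 25 besides rpl-3 and rpl-35 included the divergent pair F44E5.4 and F44E5.5, near-identical genes of the heat shock 70 family between whose starts one peak lay (II, 11759311 to 11759574, signal 179.8). Of the 30-base words in that peak, 12.3% are repeated in the genome. The list also had mog-4, a helicase of germline sex determination (II, 14561729 to 14561992, summit minus TSS -262 bp, signal 169.7), eif-3.G, a translation initiation factor subunit for which summit minus TSS is -1044 bp (II, 8441591 to 8441854, in an intron of lips-10, signal 162), and F56G4.6 with wbp-4 (I, 11374312 to 11374575, signal 154). The ubiquitin ligase gene eel-1 (IV, 3050347 to 3050610, -375 bp, signal 146) and tasp-1 with K01G5.10 (III, 10759129 to 10759392, signal 141) followed. The other peaks were distal or beside less studied loci: K07D4.1 (II, 4047941 to 4048204, signal 185), ccm-2 (IV, 1831250 to 1831513, in an intron of cmk-1, signal 172), W02H3.t1 (X, 11094062 to 11094325, -1479 bp, signal 169.0) and C36E6.8 (X, 17442631 to 17442894, signal 152). Repeated 30-base words made up 99.6% of the peak near C36E6.8, 77.9% of that near ccm-2, 52.8% of that near Y106G6H.10, 48.1% of that near K07D4.1, and 34.0% of those at mog-4 and eel-1, so the position of these reads is uncertain.

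Short words known from worm and receptor binding sites were compared within 100 bp of the summits and in 6100 ranked peaks matched on location class and GC content. The half-site AGGTCA, bound by many nuclear receptors, was in 48 of 610 peaks (7.87%) against 6.64% of the matched peaks (odds ratio 1.20, 95% interval 0.880 to 1.64, Fisher's exact test, adjusted exact p = 0.711 over 12 words). Its longer form AAGGTCA was in 21 peaks (3.44%) against 1.7% (odds ratio 2.06, 95% interval 1.28 to 3.31, raw exact p = 0.0066, adjusted exact p = 0.0792). None of the 12 words passed after adjustment, and 2 had an unadjusted p under 0.05, AAGGTCA and TGCACA (odds ratio 0.738, raw exact p = 0.0467). Within 50 bp of the summit AAGGTCA passed (odds ratio 2.54, adjusted exact p = 0.0408). Its odds ratio was 1.34 within 200 bp (adjusted exact p = 0.598) and 1.34 away from short RNA genes, a setting chosen after seeing the data (adjusted exact p = 0.875). In the list of replicate 1 alone it was 0.41 (1 of 89 peaks, 95% interval 0.0548 to 3.07), and in that of replicate 2 alone 1.97 (5 of 96, 0.740 to 5.26). Against ranked peaks not matched on GC and location, 6 words passed. AGGTCA (odds ratio 1.58, adjusted exact p = 0.0148), AAGGTCA (odds ratio 2.08, adjusted exact p = 0.0128) and GAGAGAG (1.98) were more frequent in the peaks. TTTCAAA (odds ratio 0.466, adjusted exact p = 2.01e-09), TGATAA (0.595) and AGTTCA (0.692) were less frequent.

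When all 2080 words of 6 bases were compared, 83 were more frequent in the peaks and 47 less frequent. The leading words were CGAACC (16.9% against 6.44%, odds ratio 2.95, adjusted exact p = 1.91e-13), GTTCGA (19% against 8.97%, odds ratio 2.38) and GAACCC (99 of 610 peaks against 7.67%, odds ratio 2.33). The matched peaks were not chosen by nearness to tRNA genes, so sequence that tRNA genes share cannot be told apart from a preference of NHR-120. Among the 448 peaks with no tRNA, snoRNA, snRNA, rRNA or microRNA start within 1 kb, a subset chosen after seeing the data, 4 words were more frequent, CGCGCA (13.2% against 5.25%, odds ratio 2.74, adjusted exact p = 3.76e-06), GCGCGC, GCGCAC and AGCGCG, and 2 were less frequent. CGAACC, GTTCGA and GAACCC did not pass in this subset.

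The nhr-120 gene (X, 6636561 to 6640620, minus strand), which the transgene carries, had 4 thresholded peaks within 20 kb, and 6 in the conservative list. Windows of the same width placed freely on X, a count chosen after seeing the data, held as many in 2 other stretches, with summits from 1344996 to 1379582 and from 16902017 to 16932537, and 402 adjoining windows laid from the chromosome's start held at most 3. Each of these 2 stretches includes a pair of overlapping peaks (signals 79.9 and 8.59 in the first, 56.1 and 4.23 in the second), whereas the 4 at nhr-120 do not overlap. Within 50 kb nhr-120 had 5 peaks (7 in the conservative list), and 1 other stretch of X held as many as 5, counting the overlapping pair with signals of 56.1 and 4.23. Other stretches were not counted in the conservative list. The 4 peaks lay in an intron of nhr-120 (6638077 to 6638340, signal 89.3), in its exon (6639211 to 6639474, signal 87.8), upstream of it (6643550 to 6643813, signal 78.6) and over an exon of the neighbour nhr-173 (6656711 to 6656974, signal 80.9). They ranked between 166 and 307 by signal in the list. The 42 ranked peaks within 20 kb had a median signal of 28.7, against 22.8 for ranked peaks on X. The unc-119 locus (III, 10902641 to 10908935), which the transgene also carries, had no thresholded peak within 20 or 50 kb, and its 35 ranked peaks within 20 kb had a median signal of 25.6 against 23 on its chromosome (22.3 within 50 kb).

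**Figure D3:**
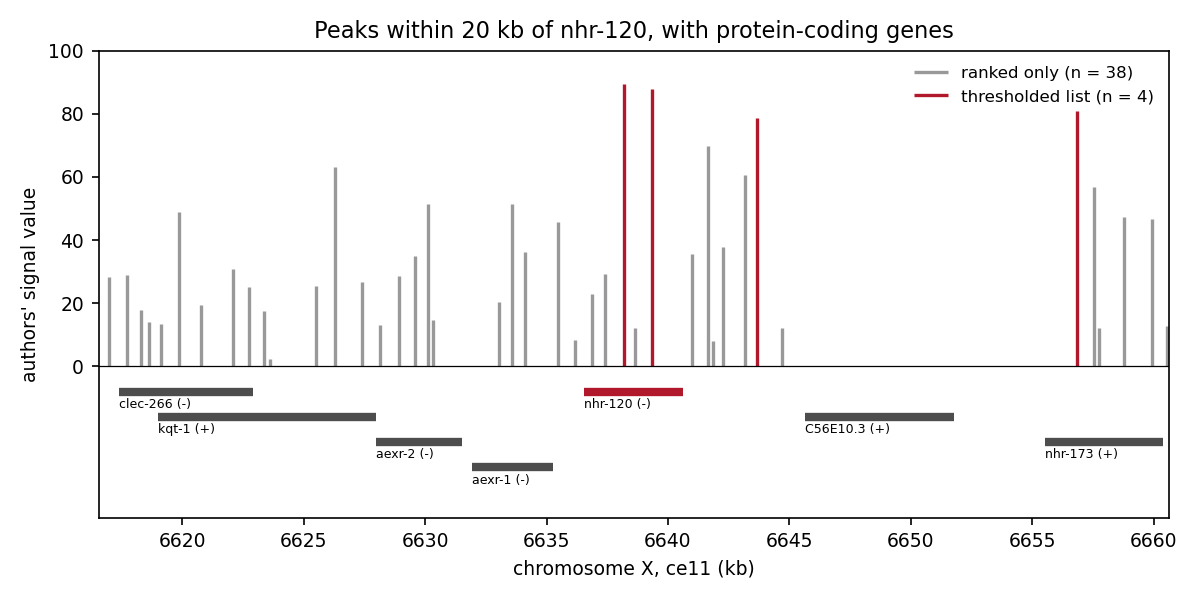
Ranked peaks within 20 kb of nhr-120 on chromosome X (ce11, kb), drawn as lines at their summits with the authors' signal value as height, and the protein-coding genes below with their strand. The 4 thresholded peaks are in red, with signals from 78.6 to 89.3.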

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

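The tests of transgene copies and of clustering for the unlisted peaks were chosen after the result was seen. A signal outside the main list drew attention: 97 of the 707 ranked peaks with a global IDR of at most 0.01 are not in the thresholded list, and they include the strongest peaks of the experiment. The highest had a signal of 3680 (X, 15810952 to 15811191, intergenic), 12.9 times the highest signal of the main list, and 12 of the 97 exceeded that highest value. The next strongest were at V, 5284100 to 5284266 (signal 762) and X, 293347 to 293462 (signal 754). Repeated sequence is a candidate source: a median of 90.2% of the 30-base words in these peaks occur more than once in the genome, against a median of 0% in 2000 random ranked peaks, and 73.2% of the 97 have another of them within 10 kb, against 2.27% among random ranked peaks. Extra copies of the transgene are argued against, as 0% of them lie within 50 kb of nhr-120 or unc-119. Whether they were removed by the input that only the thresholded lists have stays open, and no biological explanation was tested.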

How the results depend on the processing

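The settings without peaks near tRNA or short RNA genes, without piRNA genes, with the IDR limit of 0.001 and with all 707 ranked peaks past 0.01 were chosen after seeing the data. Enrichment of tRNA genes (odds ratios 10 to 18.1) and snoRNA genes (5.62 to 17.7) passed in all 9 alternatives run for each, as did the depletion of exons (0.302 to 0.721) and introns (0.271 to 0.578) in all 8. Ribosomal protein genes passed in 9 of 10 (3.52 to 14.3), snRNA genes in 5 of 9 (2.07 to 9.48), protein-coding starts in 4 of 8 and chromosomes X and II in 3 of 6 each. An IDR of at most 0.001 left 98 of the 610 peaks, and a limit of 0.01 removed none, because it equals the authors' threshold. The single replicates' lists held 89 to 96 peaks. In the upper 50% of each replicate list by signal, 23 peaks were shared, as fewer entered. The Spearman correlation over all ranked peaks was 0.255. Chromosomes passing numbered 0 in both single-replicate lists, which hold fewer peaks, and 0 away from tRNA genes. Away from short RNA genes, 1 of the gene lists passed, because the RNA-gene lists were left out. For words, 1 passed in the 50 bp window and 6 against the unmatched background; the cause was not tested. In the lists of the single replicates, the odds ratio of protein-coding starts turned in both (0.961 to 0.998). Those of chromosome II (0.933 to 1.06), AGGTCA (0.786 to 1.17) and AAGGTCA (0.41 to 1.97) turned only without replicate 2 (1.06, 0.786 and 0.41), and that of the collagen list (0.869 to 2.05) only without replicate 1. Odds ratios also turned for non-coding RNA starts away from short RNA genes (0.663), X away from tRNA genes (0.915) and AGGTCA at 200 bp (0.943). Beyond what the removed peaks themselves show, the cause was not tested. No paired analysis was possible because the series has 1 group. Depth is unknown, so how it limits the number of peaks was not assessed.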

Other observations

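The tests of tRNA and snoRNA genes taken apart, of transgene copies at nhr-120, of tRNA isotypes and of tRNA genes on X were chosen after the result was seen. The tRNA peaks were spread over isotypes. Between 37.8% of lysine tRNA genes (17 of 45) and 5% of asparagine tRNA genes (1 of 20) were marked among isotypes with at least 20 tested genes, and none of 21 isotypes differed from the rest after adjustment (Fisher's exact test, smallest adjusted exact p = 0.277), with 2 at an unadjusted p under 0.05. These were arginine (4 of 44, raw exact p = 0.0164) and lysine (raw exact p = 0.0264). On chromosome X, 77 of 272 tRNA genes (28.3%) were marked, against 61 of 318 (19.2%) on the autosomes (odds ratio 1.66, 95% interval 1.13 to 2.44, Fisher's exact test, p = 0.0111). Neighbouring tRNA genes share peaks, so the genes are not independent in these tests. By peak, 53 of 581 ranked peaks near tRNA genes on X were thresholded (9.12%), against 47 of 763 (6.16%) on the autosomes (odds ratio 1.53, 95% interval 1.02 to 2.3, Fisher's exact test, p = 0.046). Signals at snoRNA peaks had a median of 89.7 and at tRNA peaks of 82.3, against 76.6 for the 448 peaks away from short RNA genes.

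The peaks at tRNA and snoRNA genes are the pattern most worth a second look, since they make up 150 of the 610 peaks. GC content is argued against: against ranked peaks of the same GC decile the odds ratio was 13.5 (95% interval 10.5 to 17.3). Reads shared between repeated copies stay open for the 2 classes together (median 21.3% repeated words). Among peaks with under 10% of repeated words, snoRNA genes kept an odds ratio of 15.3 (95% interval 8.55 to 27.2). Shared reads therefore cannot account for the snoRNA peaks. For tRNA genes the odds ratio was 2.33 (95% interval 1.08 to 5.02), which cannot decide the question. Peaks on tRNA genes hold the genes' own repeated sequence (median 23.6% of words). The limit therefore kept only 10 of the 100 tRNA peaks, and would do so whether or not reads were shared. Summits inside the gene made up 67% of these peaks and 15.5% of other ranked peaks near tRNA genes. Shared reads stay open for tRNA genes. Occupancy that does not need NHR-120, such as open and heavily transcribed chromatin precipitated in any such experiment, cannot be told apart from binding, because 0 other groups are at hand. No biological explanation was tested.

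At the nhr-120 gene, extra copies of the transgene may raise the signal of the whole region. The median signal of ranked peaks within 20 kb was at percentile 98.5 of windows of the same width on X, and within 50 kb at percentile 100. At unc-119, of which the transgene also carries a copy, it was at percentile 83.8 of its chromosome within 20 kb and 29.5 within 50 kb. How much sequence around either gene the transgene holds was not examined, so the unc-119 values cannot weigh against extra copies, which stay open. For nhr-120, shared reads are argued against by a median of 0% repeated 30-base words in the 4 peaks. Binding of the receptor to its own gene was not tested and stays open.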
